A study of Mus musculus with 12 samples.

How the data were processed

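The 12 libraries analysed were each made from flow sorted CD45+ cells of metastatic mouse lung, with 3 libraries from each of 4 treatments. Per the labels, the libraries were made with the Chromium 3' dual-index chemistry (version 3.1) and sequenced together on NovaSeq lanes. The authors deposited raw UMI counts per gene and cell barcode, as filtered matrices; the values are whole numbers. The submitters' processing notes name Cell Ranger 4.0 and 5.0 and the genome build GRCm39, without saying what each version was used for. The number of animals behind a library is not given in the sources used here, so p-values measure only the spread between these libraries, part of which may be technical. The doses and the duration of treatment are likewise not given in the sources used here. Gene names are those that the deposited files pair with their identifiers; 28 of the symbols belong to more than 1 identifier, and identifiers were kept apart throughout. No coordinates are reported.

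Barcodes with fewer than 200 detected genes, fewer than 500 UMIs or more than 15% of UMIs from mitochondrial genes were removed, which took out 2577 of 58984 barcodes. Doublets were scored per library with Scrublet as built into scanpy 1.11.5. Its automatic threshold was used in 5 libraries. In the other 7 it marked under 0.5% of barcodes, and the top scores were removed instead, in proportion to the number of barcodes (3.52% to 4.395% of them). This removed 1898 barcodes and left 54509 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering (leidenalg 0.10.2, resolution 1.0, Python 3.11.15). No batch integration was applied.

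Clusters were called "X-like" from marker genes fixed before the data were examined, as were the groups, the tests, the gene lists, the rule for naming genes and the alternatives to each choice. A cluster took the class whose markers had the highest mean log2 enrichment, with at least 3 markers enriched 2-fold. Classes within 0.75 of the highest were told apart by their markers among the 10 leading genes. An NK cell or ILC2 cluster was taken as T cell if its lowest CD3 gene averaged at least 1 scaled count per cell. This level was taken before the log transformation. These thresholds and those for leaving a cluster unnamed were set after the clusters' scores had been seen. A cluster stayed unnamed if a second lineage scored at least 0.55 of the first, if its thymocyte genes (a list added after the clusters were seen, holding genes such as Rag1 and Dntt) scored 2 or more, or if its leading 10 genes held more markers of another class than of its own. Clusters left unnamed for thymocyte genes held 23.5% ± 39.1 of cells in vehicle (mean ± SD, n = 3), 27.7% ± 32.1 in GW3965, 11.9% ± 19.2 in 27HC and 0.326% ± 0.0814 in GW273297X. Those left unnamed for leading genes of another class held on average 0.433%, 0.088%, 0.999% and 0.28%, and those with markers of 2 lineages 0.76%, 0.433%, 0.604% and 1.17%, in the same order. No cluster met the rule for alveolar macrophage-like cells, so 6 of the 7 planned classes were tested for expression.

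For each class, raw counts were summed per library over the cells of the class, using libraries with at least 20 cells of it. The 2 libraries below this for conventional dendritic cell-like cells were vehicle replicate 3 and 27HC replicate 2, which left 10 libraries for that class. The sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood F test), in 1 fit over all 4 groups so that the spread was estimated from all libraries. Each of the 4 comparisons was a contrast in that fit, and a further test with 3 degrees of freedom asked whether a gene differed among the groups. P-values were adjusted by the Benjamini-Hochberg method within each class and comparison, and a gene was called below an adjusted p of 0.05. Levels are CPM (counts scaled by the effective library size of the class), given as mean ± SD. The standard error (SE) of a log2 fold change was taken from the F statistic, and intervals are 95%. All tests are two-sided.

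The share of each class among kept cells was tested with the same edgeR test on cell counts, without TMM factors, for the 9 classes with a mean of at least 10 cells per library. An exact permutation test of the shares was run beside it; with 3 libraries against 3 its smallest possible p is 0.1. Shares of single libraries carry 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only. Groups of 3 that do not overlap arise in 10% of comparisons by chance.

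Gene lists (24 in all) were written before the data were examined. They cover LXR targets; cholesterol synthesis and uptake under SREBP2; interferon-stimulated genes; interferon-gamma and guanylate-binding genes; inflammatory cytokines and NF-kB; alternative activation and immunosuppression; MHC class II presentation; hypoxia and glycolysis; cell cycle; immediate-early genes; mitochondrially encoded genes; immature neutrophil granule genes; aged or tumor-associated neutrophil genes; naive, regulatory, CD8 and gamma-delta T cells; T cell activation; and RNA that marks neutrophils, macrophages, T cells, B cells, erythrocytes or epithelium. A list was tested in a class with at least 5 of its genes by camera (limma 3.58.1, voom weights), with the preset inter-gene correlation of 0.01, adjusted over the lists of that class and comparison. camera with an estimated correlation and fry were run beside it. A list's value is the median edgeR log2 fold change of its tested genes, and single genes were also "adjusted over the list alone". The list score of a library is the mean log2 CPM of the list's genes. The 4 listed symbols Cd163l1, Tcrg-C1, Mx1 and Mx2 matched no gene name in the files.

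Genes named in the text follow a fixed rule. The LXR targets Abca1, Abcg1, Srebf1, Mylip, Nr1h3, Apoe, Lpcat3, Scd1 and Scd2 are reported in monocyte-macrophage-like cells whatever their test. Called genes with a mean of at least 10 CPM and no overlap between the groups are named by size of change, up to 5 per direction (2 in conventional dendritic, B and NK cell-like cells). List members are named where they pass, and where no gene passed in a class, the 2 genes with the smallest p are named. Immunoglobulin and T cell receptor segments and unnamed gene models were left out of this ranking. The results of 1 gene that this rule would name are not reported here. List members shown as examples, and members of clusters, were chosen after their values were seen.

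Alternatives were DESeq2 1.42.0 (Wald or likelihood ratio test) in place of edgeR, its size factors in place of TMM, no filter on low counts, only the 2 groups compared, the replicate number as a term, doublets kept, a Leiden resolution of 0.5, and each library left out in turn. After the data had been seen, 3 more were added. These leave out the 4 libraries with over 10% of cells in thymocyte-gene clusters, take that share as a covariate, or count shares among named classes only.

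The procedure was tested on simulated counts for GW3965 against vehicle with 100 genes changed at each of 2 sizes. At a log2 fold change of 1, edgeR recovered 50 of 100 among 10569 neutrophil-like, 24 among 10321 monocyte-macrophage-like, 19 among 8964 conventional dendritic, 76 among 11552 T, 63 among 10740 B and 71 among 9333 NK cell-like genes; at 2 it recovered 79, 75, 70, 90, 90 and 92. False calls numbered 3 to 14 per class with edgeR and 6 to 28 with DESeq2, the 28 in T cell-like cells. A raised list was called in all 6 classes with the preset and the estimated correlation. With the preset correlation, 0 of 20 unchanged lists were called in each class. The simulated genes were drawn independently of each other. The simulation therefore cannot show how either setting behaves where genes vary together. A 4-fold rise in the share of NK cell-like cells was called in 20 of 20 simulations, with 2 false calls. The spread between libraries in these simulations was fixed, not estimated from the data, so they do not show the power of the share tests here. In the data, the log2 fold change of this share for GW3965 against vehicle had an SE of 0.753. Figures were drawn with matplotlib 3.10.9.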

Results

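CD45+ immune cells sorted from mouse lungs bearing metastatic tumours were profiled one by one, to ask how ligands of the liver X receptors (LXRs) and an inhibitor of CYP27A1 alter the immune environment of breast tumour metastases. LXRs are nuclear receptors that sense oxidised cholesterol and switch on genes of cholesterol export and lipid synthesis. GW3965 is a synthetic LXR agonist, 27HC is 27-hydroxycholesterol, an LXR ligand that the enzyme CYP27A1 makes from cholesterol, and GW273297X is the CYP27A1 inhibitor. Each of these treatments and the vehicle was represented by 3 libraries, 12 in all. The libraries held 35671761 to 54339549 UMIs and 4394 to 5488 cell barcodes, and 4056 to 5195 cells per library were kept, with a median of 5225 to 6998 UMIs per cell.

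The cells fell into 38 clusters. Neutrophil-like cells formed 6 of these, among them clusters led by the interferon-induced genes Isg15 and Cxcl10 and 1 led by the granule genes Camp, Ngp and Ltf. Monocyte-macrophage-like cells formed a cluster with Fn1, Ccl2 and C1qa and a smaller one with Ace, Ear2 and Cx3cr1, genes of patrolling monocytes. Conventional dendritic cell (cDC)-like cells comprised a cluster with Xcr1 and Clec9a and another with the migration genes Fscn1 and Ccl22. T cell-like cells included clusters led by Foxp3, by Il17a, by Gzmk and Icos, and by Lag3 and Ifng. B, NK, plasmacytoid dendritic (pDC), eosinophil, ILC2, plasma and basophil or mast cell-like cells made up the other named clusters. Per library there were 503 to 2835 neutrophil-like, 37 to 160 monocyte-macrophage-like, 14 to 56 cDC-like, 445 to 1396 T cell-like, 185 to 1927 B cell-like and 52 to 459 NK cell-like cells. The tests of cDC-like cells used 10 libraries, with 2 each of vehicle and 27HC. The summed counts of a class in a library ranged from 3197141 to 18143359 UMIs for neutrophil-like cells and from 837049 to 4139671 for monocyte-macrophage-like cells.

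A set of 9 clusters was set apart by a score of thymocyte genes, such as Rag1 (recombination of antigen receptor genes) and Dntt (addition of bases at the joints). One of them, cluster 11, had little of either, with Rag1 at 0.174 per 10000 counts against 0.3906 in monocyte-macrophage-like cluster 13. Cluster 30 scored higher for neutrophil markers (4.487) than for T cell markers (1.898), and cluster 35 higher for B cell markers (5.105 against 1.672). Of the 11, 20 and 14 cells of the set in GW273297X replicates 1, 2 and 3, cluster 30 held 2, 11 and 12. The 9 clusters together held 68.6% of the cells of vehicle replicate 2 (95% exact binomial interval 67.2 to 70.0), 63.0% of GW3965 replicate 3 (61.6 to 64.3), 34.1% of 27HC replicate 3 (32.6 to 35.6) and 19.7% of GW3965 replicate 1 (18.5 to 21.0). In the other 8 libraries they held at most 1.51%. They belong to no named class, and they lower every other share in those 4 libraries. The T cell-like cells of those libraries also held more Rag1. It stood at 0.192, 0.0896, 0.14 and 0.0566 per 10000 counts in vehicle replicate 2, GW3965 replicate 3, 27HC replicate 3 and GW3965 replicate 1. In each other library it was at most 0.00199. The expression tests of named classes may therefore carry some thymocyte RNA in those libraries.

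**Figure D1:**
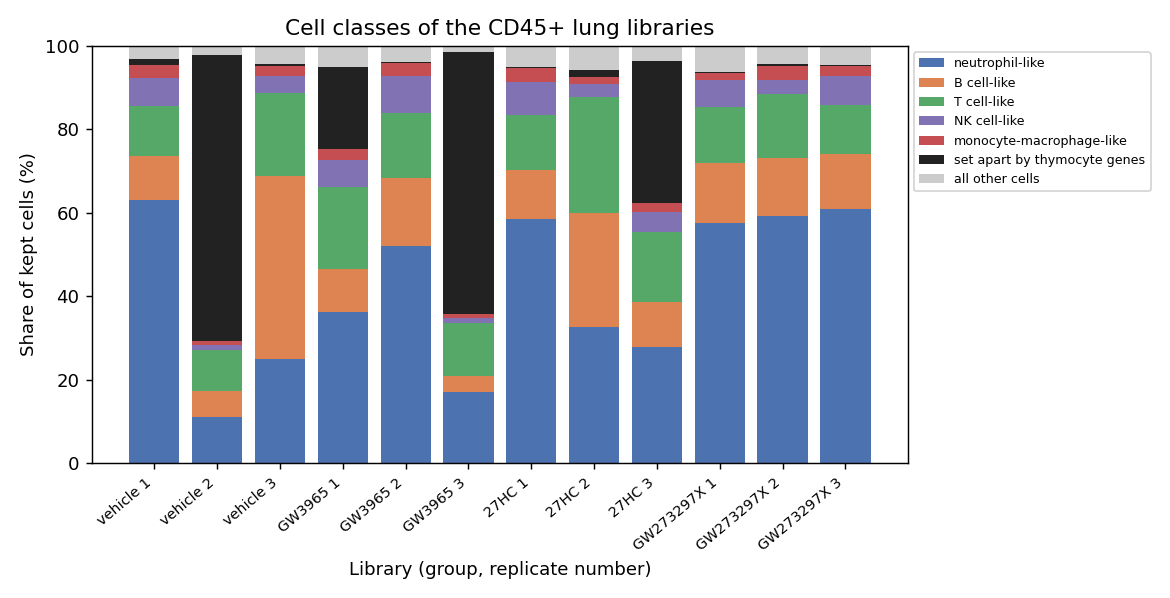
Share of kept cells (%) by class in each of the 12 libraries, as stacked bars. The black part is the clusters set apart by thymocyte genes, which reached 68.6% in vehicle replicate 2; neutrophil-like cells took 57.5 to 60.9% in the GW273297X libraries and 11.1 to 63.0% in the vehicle libraries.

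The composition of the immune infiltrate is the broadest way in which the treatments could differ. Neutrophil-like cells made up 33.1% ± 26.9 (mean ± SD, n = 3) of kept cells with vehicle, 35.1% ± 17.4 with GW3965, 39.7% ± 16.6 with 27HC and 59.2% ± 1.70 with GW273297X. By edgeR the last did not differ from vehicle (adjusted p = 0.755). B cell-like cells made up 20.2% ± 20.6, 10.1% ± 6.24, 16.7% ± 9.35 and 13.9% ± 0.651, and 1 vehicle library reached 43.9%. T cell-like cells took 13.9% ± 5.21, 15.9% ± 3.49, 19.2% ± 7.65 and 13.5% ± 1.76, and monocyte-macrophage-like cells 2.11% ± 1.08, 2.12% ± 1.21, 2.43% ± 0.797 and 2.49% ± 0.843. The pDC-like cells, a source of type I interferon, took 0.474% ± 0.24 with vehicle and 0.987% ± 0.563 with GW3965. Their share was 1.03% ± 0.218 with 27HC (edgeR adjusted p = 0.745) and 1.12% ± 0.136 with GW273297X (edgeR adjusted p = 0.555). Both of these lay above vehicle in every library (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). Counted among named classes only, which leaves out the thymocyte-gene clusters, the pDC-like share was 0.895% ± 0.815 with vehicle, 1.23% ± 0.397 with 27HC and 1.14% ± 0.141 with GW273297X, and that separation was lost (exact permutation p = 0.6 and 0.7, two-sided). T cell-like cells counted in this way took 21.6% ± 9.89, 24.9% ± 9.31, 22.7% ± 8.37 and 13.7% ± 1.8 with vehicle, GW3965, 27HC and GW273297X. None of the 9 classes tested changed its share in any of the 4 comparisons by edgeR, and 0 reached an unadjusted p under 0.05; DESeq2 was not used for shares.

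GW3965 against vehicle asks what a synthetic LXR agonist does to the cells. The direct targets of LXR were read in monocyte-macrophage-like cells, where cholesterol export is most active. Abca1, which exports cholesterol to apolipoproteins, stood at 41.2 ± 16.2 CPM with GW3965 and 24.5 ± 12.7 CPM with vehicle, a log2 fold change of 0.757 (SE 0.518; edgeR adjusted p = 0.999; 95% interval -0.38 to 1.89). Abcg1, the exporter to HDL particles, stood at 92.6 ± 18.2 against 83.6 ± 21.9 CPM, a log2 fold change of 0.146 with an interval of -0.337 to 0.628. For Srebf1 (fatty acid synthesis), Mylip (degradation of the LDL receptor), Nr1h3 (LXR alpha itself) and Apoe (the lipid carrier apolipoprotein E) the log2 fold changes were -0.0325, 0.0225, -0.37 and 0.0998. Lpcat3 (membrane phospholipids) differed by -0.249, with no overlap between the groups (19.6 to 25.8 against 26 to 27.8 CPM). The desaturases Scd1 and Scd2 differed by -1.32 and 0.269. Scd1 differed by 0.0553 without vehicle replicate 3, which held 48 CPM against 6.3 and 11.3 in the other vehicle libraries. The list of 21 LXR targets had a median log2 fold change of 0.0225, with 11 genes higher (camera adjusted p = 0.88) and 0 adjusted over the list alone. Its median turned to -0.0176 without GW3965 replicate 3, to -0.0146 with doublets kept and to -0.0779 without the 4 libraries rich in thymocyte-gene cells.

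No gene passed edgeR in neutrophil-, monocyte-macrophage-, cDC-, T cell- or B cell-like cells under GW3965, that is 0 calls in each, beside 378, 393, 554, 731 and 331 genes at an unadjusted p under 0.05 and 0, 0, 6, 1 and 0 calls by DESeq2. In NK cell-like cells 1 of 9333 genes rose. Krt83 (ENSMUSG00000067613.7), a hair keratin, reached 25.9 ± 10.2 CPM against 8.8 ± 4.76 with vehicle, a log2 fold change of 2.04 (SE 0.308, edgeR adjusted p = 0.00424). All 3 treated libraries lay above all 3 vehicle libraries, but GW3965 replicate 3 (14.5 CPM) only just above vehicle replicate 2 (14.3 CPM). These 2 libraries held 62 and 52 NK cell-like cells. The call was lost without vehicle replicate 1 (edgeR adjusted p = 0.36), GW3965 replicate 2 (0.22) or vehicle replicate 3 (0.117). DESeq2 kept it (adjusted p = 0.0319), and a fit of the 2 groups alone did not (edgeR adjusted p = 0.0779). In monocyte-macrophage-like cells the 2 genes with the smallest p were Slfn9, an interferon-induced Schlafen gene, and Tgtp2, an interferon-induced GTPase, with log2 fold changes of 1.18 (SE 0.206) and 1.56 (SE 0.32), each at an edgeR adjusted p of 0.943. Those of neutrophil-like cells were the viral RNA sensor Ifih1 (0.507, SE 0.112) and the chromatin reader Ing5 (-0.898, SE 0.194), each at an edgeR adjusted p of 1. In cDC-like cells Phlda1, a brake on survival signalling, was lower by a log2 fold change of -2.28 (SE 0.419) and the selenoprotein Selenom by -2.21 (SE 0.41), each at an edgeR adjusted p of 0.679. T cell-like cells had less Cd40lg, the helper ligand for CD40 (-0.808, SE 0.14; edgeR adjusted p = 0.771), and less of the folding enzyme Ppic (-1.02, SE 0.207; 0.774). In B cell-like cells the first were the costimulatory receptor Tnfrsf9 (3.65, SE 0.879, at 1.26, 3.96 and 0 CPM with GW3965 and 0.233, 0 and 0.174 CPM with vehicle; 2.22 without GW3965 replicate 2) and the early-response repressor Nab2 (-0.688, SE 0.17), each at an edgeR adjusted p of 1.

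Genes induced by interferons, the signals of antiviral defence, stood higher with GW3965. All 28 interferon-stimulated genes were higher in monocyte-macrophage-like cells, with a median log2 fold change of 0.743 (camera adjusted p = 1.96e-30, and adjusted p = 0.0821 with an estimated correlation), and 16 of them passed when adjusted over the list alone, against 0 over all genes tested. Among the 16 were Phf11b (1.01, SE 0.208), Ifit2, which blocks translation of viral RNA (1.29, SE 0.282), the tethering protein Bst2 (1.25, SE 0.305), the T cell attractant Cxcl10 (1.46, SE 0.37) and Oasl2 (1.25, SE 0.318). The list scored 7.90 ± 0.105 with GW3965 and 7.04 ± 0.419 with vehicle on the log2 CPM scale, without overlap (exact permutation p = 0.1, two-sided). The interferon-gamma and guanylate-binding genes were higher by a median of 0.696, 19 of 20 genes (camera adjusted p = 8.3e-20, and adjusted p = 0.0821 with an estimated correlation), and 13 passed when adjusted over the list alone. Hypoxia and glycolysis genes were higher by 0.358 (17 of 18 genes; camera adjusted p = 4.02e-07, and adjusted p = 0.403 with an estimated correlation). RNA that marks B cells was lower in the same cells, by -1.64 (all 9 genes; camera adjusted p = 2.08e-05, and adjusted p = 0.403 with an estimated correlation), and by -0.492 without vehicle replicate 3. In neutrophil-like cells all 28 interferon-stimulated genes were higher, by 0.402 (camera adjusted p = 2.66e-13, and adjusted p = 0.265 with an estimated correlation), or by 0.178 without vehicle replicate 3. The neutrophil-like cluster led by Isg15 held 524 of 1472, 618 of 2699 and 121 of 828 such cells in GW3965 replicates 1, 2 and 3. With vehicle it held 706 of 2658, 65 of 503 and 211 of 1099. The cluster of patrolling monocyte genes made up 18.3% ± 1.45 of the monocyte-macrophage-like cells with GW3965, 17.3% ± 9.15 with 27HC and 27.8% ± 14.3 with vehicle.

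In T cell-like cells all 11 naive T cell genes were lower under GW3965, with a median of -0.434 (camera adjusted p = 3.48e-08, and adjusted p = 0.244 with an estimated correlation). The 3 that passed when adjusted over the list alone were Tcf7, a factor of naive and memory cells (-0.434, SE 0.125), Dapl1 (-1.61, SE 0.437) and Igfbp4 (-1.09, SE 0.315). The CD8 T cell genes were higher by 0.631 (7 of 8 genes; camera adjusted p = 7.75e-06, and adjusted p = 0.141 with an estimated correlation). These values sit beside a different mix of clusters, since cluster 6, which carries such naive genes, held 23.5% ± 7.27 of the T cell-like cells with GW3965 and 38.4% ± 11.4 with vehicle. Cluster 8 held 25.8% ± 11.8 with GW3965, and exceeded cluster 6 in GW3965 replicate 3 alone of the GW3965 libraries, at 39.2%. In vehicle replicates 1, 2 and 3 cluster 8 held 108 of 510, 120 of 445 and 245 of 869 T cell-like cells, much the same share. It exceeded cluster 6 in vehicle replicate 2 as well, by 120 to 118 cells. In NK cell-like cells the cholesterol synthesis genes under SREBP2 were higher by a median of 0.519 (20 of 22 genes; camera adjusted p = 2.33e-10, and adjusted p = 0.106 with an estimated correlation). Of these, 7 passed when adjusted over the list alone, among them Cyp51 (1.01, SE 0.243) and Sqle (1.47, SE 0.533), both enzymes of sterol synthesis, and Srebf2, the master regulator (0.514, SE 0.159). Over all classes, 52 of 130 list tests passed with the preset correlation, and 0 did with an estimated correlation or with fry.

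27HC against vehicle asks the same of a natural ligand. No direct LXR target passed in monocyte-macrophage-like cells. Abca1 stood at 13.4 ± 8.16 CPM against 24.5 ± 12.7, a log2 fold change of -0.823 (SE 0.536; edgeR adjusted p = 0.999; interval -2 to 0.354), and Abcg1 at 68.2 ± 15.7 against 83.6 ± 21.9 CPM (-0.286). Nr1h3 was lower by -0.863 (SE 0.51). Its highest 27HC library, at 15.7 CPM, lay just below its lowest vehicle library, at 15.9 CPM. Srebf1 was lower by -0.258, Mylip by -0.173 and Apoe by -0.167. Lpcat3 differed by 0.0473, Scd2 by 0.592 and Scd1 by -0.892, or by 0.494 without vehicle replicate 3. The LXR list had a median of -0.136, with 8 of 21 genes higher (camera adjusted p = 0.677) and 0 adjusted over the list alone. Without 27HC replicate 1 that median was 0.0178.

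Under 27HC edgeR called 0 genes in each of the 6 classes. At an unadjusted p under 0.05 there were 249 in neutrophil-, 347 in monocyte-macrophage-, 457 in cDC-, 233 in T cell-, 144 in B cell- and 411 in NK cell-like cells. DESeq2 called 1, in monocyte-macrophage-like cells, and 0 in the others. The smallest p of monocyte-macrophage-like cells belonged to Folr2, a folate receptor of resident macrophages (-4.31, SE 0.884, from 16.9 ± 12.8 CPM with vehicle to 0.67 ± 0.585), and to Retn, which encodes resistin (-2.17, SE 0.46), each at an edgeR adjusted p of 0.999. NK cell-like cells had less Rasgrp2, an activator of the integrin switch Rap1 (-0.561, SE 0.132; edgeR adjusted p = 0.607). The mitotic kinase Plk1 (2.35, SE 0.521) and Phlda1 (-2.04, SE 0.464) led in cDC-like cells at an edgeR adjusted p of 0.895. In T cell-like cells Brpf3 (histone acetylation; -0.582, SE 0.125) and Cd274, which encodes the checkpoint ligand PD-L1 (0.51, SE 0.139), led at an edgeR adjusted p of 1. The plasma cell proteoglycan Sdc1 (-1.43) and the Golgi protein Golm1 (-0.65) led in B cell-like cells, and the transglutaminase Tgm3 (-2.47) and Krt83 (-1.53) in neutrophil-like cells, again at an edgeR adjusted p of 1.

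Genes of sterol synthesis, which cells switch on when short of cholesterol, stood higher with 27HC. All 22 genes of the SREBP2 list were higher in monocyte-macrophage-like cells, by a median of 0.493 (camera adjusted p = 4.54e-10, and adjusted p = 0.355 with an estimated correlation), although 0 passed when adjusted over the list alone. Cyp51 was higher by 1.03 (SE 0.309), Hmgcs1, which makes a precursor of sterols, by 0.736 (SE 0.242) and Insig1, which restrains the pathway, by 0.621 (SE 0.216). The list scored 4.82 ± 0.158 against 4.30 ± 0.045 with vehicle, without overlap (exact permutation p = 0.1, two-sided). In NK cell-like cells the same list was higher by 0.443 (18 of 22 genes, camera adjusted p = 9.56e-07, and adjusted p = 0.306 with an estimated correlation), with 4 genes past the threshold adjusted over the list alone. The rise of this list in NK cell-like cells under GW3965 was measured against the same vehicle libraries, so the repeat is not independent. Interferon-gamma and guanylate-binding genes in monocyte-macrophage-like cells were higher by 0.456 (18 of 20 genes; camera adjusted p = 2.73e-10, and adjusted p = 0.355 with an estimated correlation), or by 0.294 without vehicle replicate 3. The interferon-stimulated genes were higher by only 0.228 (21 of 28 genes; camera adjusted p = 0.00101, and adjusted p = 0.577 with an estimated correlation). This call was lost without vehicle replicate 2 (median 0.125, camera adjusted p = 0.182), vehicle replicate 3 (0.104, 0.112) or 27HC replicate 3 (0.0936, 0.0564), and the median was 0.525 without vehicle replicate 1. B cell RNA in the same cells was lower by -1.49 (all 9 genes; camera adjusted p = 4.65e-06, and adjusted p = 0.574 with an estimated correlation), and was not called without vehicle replicate 3 (-0.585, camera adjusted p = 0.0679). In all, 41 of 130 list tests passed with the preset correlation, and 0 with an estimated correlation or with fry.

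GW273297X against vehicle asks what happens when CYP27A1 is inhibited, which would lower the supply of 27HC. Again no LXR target passed in monocyte-macrophage-like cells. Abca1 stood at 19.7 ± 9.1 CPM (log2 fold change -0.226, SE 0.522; edgeR adjusted p = 0.979; interval -1.37 to 0.92) and Abcg1 at 95.2 ± 4.47 CPM (0.198). Srebf1 differed by 0.067, Mylip by -0.0741, Nr1h3 by -0.0956, Apoe by -0.273, Lpcat3 by -0.153 and Scd2 by 0.121. Scd1 was lower by -1.57 (SE 0.678; edgeR adjusted p = 0.756; interval -3.06 to -0.0834), and by -0.178 without vehicle replicate 3. The LXR list had a median of -0.0598, with 9 of 21 genes higher (camera adjusted p = 0.925) and 0 adjusted over the list alone. It was 0.0454 without vehicle replicate 2, 0.0377 without the 4 libraries rich in thymocyte-gene cells and 0.0535 with the share of those cells as a covariate. In NK cell-like cells 11 of 13 LXR targets were lower, by a median of -0.312 (camera adjusted p = 0.00598, and adjusted p = 0.202 with an estimated correlation). Arl4c, which acts in cell migration (-0.533, SE 0.145), was the 1 gene to pass adjusted over the list alone. That list was no longer called without GW273297X replicate 3 (median -0.23, camera adjusted p = 0.177).

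The calls under GW273297X were 2 genes of NK cell-like cells, both higher. Osgin1 (ENSMUSG00000074063.11), a gene of the oxidative stress response, rose from 3.31 ± 2.91 to 21.2 ± 2.07 CPM (log2 fold change 2.27, SE 0.392; edgeR adjusted p = 0.0306), and Krt83 from 8.8 ± 4.76 to 23.9 ± 0.411 CPM (1.75, SE 0.313; edgeR adjusted p = 0.0306). Neither passed in DESeq2 (adjusted p = 0.108 for each). Osgin1 was lost without vehicle replicate 1 (edgeR adjusted p = 0.189), vehicle replicate 3 (0.13), GW273297X replicate 2 (0.104) or GW273297X replicate 3 (0.19). Krt83 was lost without vehicle replicate 1 (0.354), vehicle replicate 3 (0.191) or GW273297X replicate 1 (0.0548), 2 (0.113) or 3 (0.19). Krt83 was also the call under GW3965, and both comparisons used the same vehicle libraries, so the repeat is not independent.

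In the other 5 classes edgeR called 0 genes under GW273297X, beside 202 in neutrophil-, 657 in monocyte-macrophage-, 748 in cDC-, 1079 in T cell- and 277 in B cell-like cells at an unadjusted p under 0.05. DESeq2 called 0, 2, 6, 29 and 1. The 29 in T cell-like cells were adjusted over fewer genes, since DESeq2 gave 4480 of 11552 no adjusted p there. In the other comparisons of that class it left out 2. Nearest to a call was Vmp1, which acts in autophagy, in B cell-like cells (0.719, SE 0.109; edgeR adjusted p = 0.091), where Tnfrsf9 followed (3.53, SE 0.866; 1). In monocyte-macrophage-like cells the first were Mir155hg, host of the inflammatory microRNA miR-155 (2.48, SE 0.473), and Tgtp2 (1.55, SE 0.318), each at an edgeR adjusted p of 0.756. T cell-like cells had less Ttc28 (-0.784, SE 0.135) and more Nampt, which supplies NAD (0.577, SE 0.109), each at an edgeR adjusted p of 0.497. In cDC-like cells Zmynd15, a gene of the Fscn1 cluster, was lower (-2.3, SE 0.348) and the lysosomal enzyme Galc higher (1.84, SE 0.358), each at an edgeR adjusted p of 0.388. Zmynd15 passed with DESeq2 (adjusted p = 7.78e-06) and with the replicate number as a term (edgeR adjusted p = 0.000871). Without the libraries rich in thymocyte-gene cells its log2 fold change was -1.91, in a fit that keeps only 1 vehicle library of this class. The Fscn1 cluster held 29.1% ± 2.58 of these cells with GW273297X and 45.7% ± 9.41 with vehicle. The vehicle share counts vehicle replicate 3 (6 of 14 cells), which was not in the gene tests of cDC-like cells. In vehicle replicates 1 and 2 the cluster held 8 of 21 and 18 of 32 cells. In neutrophil-like cells the protease Asprv1 was higher (0.69, SE 0.171; edgeR adjusted p = 1). Clusters 0 and 2 held 24.3% ± 6.16 and 28.5% ± 9.79 of these cells with GW273297X and 29.3% ± 12.7 and 27.3% ± 13.5 with vehicle. Pdcd1, which encodes the checkpoint receptor PD-1, had 45 counts against 0 there, at least 7.34-fold higher against a floor of 3 counts over the vehicle group. T cell activation RNA as a whole was higher in these neutrophil-like cells, by a median of 0.952 (17 of 19 genes; camera adjusted p = 1.15e-10, and adjusted p = 0.155 with an estimated correlation), so the Pdcd1 counts are not assigned to neutrophils.

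In monocyte-macrophage-like cells with GW273297X, lists of interferon, hypoxia and cytokine genes were higher under the preset correlation alone. The interferon-gamma and guanylate-binding genes were all 20 higher, by a median of 0.640 (camera adjusted p = 1.42e-17, and adjusted p = 0.107 with an estimated correlation), and 14 passed when adjusted over the list alone. Among the 14 were Cd274 (1.04, SE 0.219), Gbp5, an inflammasome activator (1.23, SE 0.308), and Tgtp1 (1.84, SE 0.487). The interferon-stimulated genes were higher by 0.506 (27 of 28 genes; camera adjusted p = 1.02e-12, and adjusted p = 0.183 with an estimated correlation), or by 0.857 without vehicle replicate 1. All 18 hypoxia and glycolysis genes were higher, by 0.587 (camera adjusted p = 7.83e-12, and adjusted p = 0.141 with an estimated correlation), among them the glycolytic enzyme Pfkp (0.656, SE 0.202), the mitophagy receptor Bnip3 (1.24, SE 0.393) and the angiogenic factor Vegfa (0.956, SE 0.344). Inflammatory cytokine genes were higher by 0.423 (19 of 20 genes; camera adjusted p = 2.76e-06, and adjusted p = 0.107 with an estimated correlation), or by 0.661 without vehicle replicate 1, with the neutrophil attractant Cxcl3 at 2.56 (SE 0.832). B cell RNA in these cells was lower by -1.24 (8 of 9 genes; camera adjusted p = 0.000655, and adjusted p = 0.364 with an estimated correlation). It was not called without vehicle replicate 3 (-0.0206, camera adjusted p = 0.666) or GW273297X replicate 2 (-0.869, 0.201). Cell cycle genes were lower by -1.41 (21 of 22 genes; camera adjusted p = 0.0051, and adjusted p = 0.531 with an estimated correlation) and RNA that marks T cells by -2 (all 9 genes; camera adjusted p = 0.00804, and adjusted p = 0.52 with an estimated correlation). Both calls were lost without vehicle replicate 2, at -0.113 and -0.228. In that library 68.6% of the cells lay in thymocyte-gene clusters, and 43 cells were monocyte-macrophage-like. The cluster of patrolling monocyte genes made up 9.44% ± 3.39 of this class with GW273297X and 27.8% ± 14.3 with vehicle.

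In T cell-like cells with GW273297X, lists of activation and regulatory genes were higher under the preset correlation alone. The T cell activation, cytotoxicity and checkpoint list was higher by a median of 0.918 (21 of 22 genes; camera adjusted p = 8.08e-14, and adjusted p = 0.166 with an estimated correlation), with 12 genes past the threshold adjusted over the list alone. These included the inhibitory receptors Tigit (1.31, SE 0.308) and Ctla4 (0.846, SE 0.232) and the granzyme Gzmk (1.82, SE 0.469). All 10 regulatory T cell genes were higher, by 0.917 (camera adjusted p = 1.5e-09, and adjusted p = 0.166 with an estimated correlation), with 7 past the threshold adjusted over the list alone, among them the lineage factor Foxp3 (0.988, SE 0.307) and the suppressive cytokine Il10 (2.31, SE 0.616). Cluster 10, which Gzmk and Icos lead, held 27.1% ± 9.72 of the T cell-like cells with GW273297X and 14.1% ± 7.85 with vehicle, and the Foxp3 cluster 10.1% ± 0.337 and 7.58% ± 2.09. RNA that marks neutrophils was also higher in these T cell-like cells, by 1.68 (12 of 13 genes; camera adjusted p = 1.5e-09, and adjusted p = 0.166 with an estimated correlation), and by 3.6 without vehicle replicate 1. In the same cells all 11 mitochondrially encoded genes were lower, by -0.234 (camera adjusted p = 8.19e-05, and adjusted p = 0.257 with an estimated correlation). Immature neutrophil granule genes were higher there by 1.09 (11 of 12 genes; camera adjusted p = 7.74e-07, and adjusted p = 0.166 with an estimated correlation), or by 1.74 without vehicle replicate 1 and 0.716 without GW273297X replicate 3. The plan was to read the granule list in neutrophil-like cells, so its value here is not assigned to T cells. Macrophage RNA was higher by 1.17 (all 8 genes; camera adjusted p = 8.19e-05, and adjusted p = 0.168 with an estimated correlation), or by 0.726 without GW273297X replicate 3. Of 130 list tests, 75 passed with the preset correlation, and 0 with an estimated correlation or with fry.

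GW3965 against 27HC asks whether a synthetic and a natural ligand differ; their doses are not given in the sources used here, so a difference may be one of dose. Abca1 showed the widest gap among the LXR targets of monocyte-macrophage-like cells, at 41.2 ± 16.2 against 13.4 ± 8.16 CPM without overlap, a log2 fold change of 1.58 (SE 0.531; 95% interval 0.413 to 2.75; edgeR adjusted p = 1). Abcg1 was higher by 0.431 (interval -0.0513 to 0.914), Nr1h3 by 0.493, Apoe by 0.266, Srebf1 by 0.225 and Mylip by 0.195, and Lpcat3, Scd1 and Scd2 were lower by -0.296, -0.43 and -0.322. The LXR list had a median of 0.195, with 12 of 21 genes higher (camera adjusted p = 0.554) and 0 adjusted over the list alone. That median was -0.0881 without GW3965 replicate 3, -0.0303 without 27HC replicate 1 and -0.181 without the 4 libraries rich in thymocyte-gene cells. Its score was 5.36 ± 0.224 with GW3965, 5.26 ± 0.0963 with 27HC and 5.29 ± 0.263 with vehicle (exact permutation p = 0.6 for GW3965 against 27HC, two-sided).

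**Figure D2:**
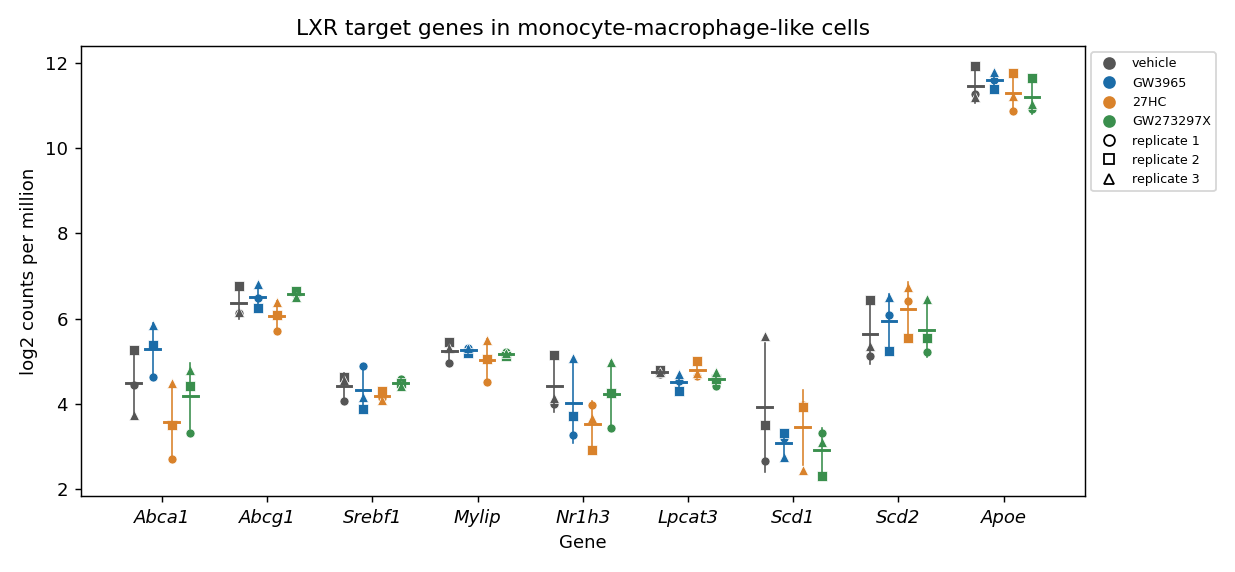
Level (log2 CPM) of 9 LXR target genes in monocyte-macrophage-like cells. Each point is a library, the horizontal line the group mean and the vertical line the SD (n = 3); Abca1 shows the widest gap between GW3965 and 27HC, and the groups overlap for most genes.

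No gene passed edgeR between the ligands: 0 in each of the 6 classes, beside 227 in neutrophil-, 279 in monocyte-macrophage-, 156 in cDC-, 451 in T cell-, 247 in B cell- and 323 in NK cell-like cells at an unadjusted p under 0.05. DESeq2 called 0, 0, 1, 1, 1 and 0. In monocyte-macrophage-like cells Folr2 (3.88, SE 0.909) and Trio, a regulator of cell shape (-0.925, SE 0.22), had the smallest p, each at an edgeR adjusted p of 1. In cDC-like cells they were the actin-capping gene Capg (-2.41, SE 0.365; edgeR adjusted p = 0.234) and the metallothionein Mt2 (-2.49, SE 0.486; 1). T cell-like cells had less Cd4, the helper coreceptor (-0.538, SE 0.0947; edgeR adjusted p = 0.929), and less Gramd4 (-0.586, SE 0.144; 0.999). B cell-like cells were led by the helicase Dqx1 (2.58, SE 0.488; edgeR adjusted p = 0.967) and the repressor Foxp4 (-0.552, SE 0.145; 1). The protocadherin Pcdh17 (1.38) and Rubcnl (-0.506) led in neutrophil-like cells, and Srm, of polyamine synthesis (-0.891), and Mthfd1, of folate metabolism (-1.03), in NK cell-like cells, each at an edgeR adjusted p of 1.

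The interferon and sterol lists differed between the ligands in monocyte-macrophage-like cells under the preset correlation alone. Interferon-stimulated genes were higher with GW3965 by a median of 0.575 (27 of 28 genes; camera adjusted p = 7.79e-19, and adjusted p = 0.249 with an estimated correlation). Their scores were 7.90 ± 0.105 with GW3965 and 7.34 ± 0.171 with 27HC, without overlap (exact permutation p = 0.1, two-sided). Genes of the SREBP2 list were lower with GW3965, by -0.297 (20 of 22 genes; camera adjusted p = 6.61e-05, and adjusted p = 0.294 with an estimated correlation). The interferon-stimulated genes were higher in neutrophil-like cells too, by 0.438 (27 of 28 genes; camera adjusted p = 3.57e-13, and adjusted p = 0.306 with an estimated correlation). The neutrophil-like cluster led by Isg15 held 524 of 1472, 618 of 2699 and 121 of 828 such cells in GW3965 replicates 1, 2 and 3. With 27HC it held 366 of 2673, 258 of 1635 and 169 of 1131. The one led by Cxcl10 held 40, 121 and 55 cells with GW3965 and 130, 51 and 69 with 27HC. In T cell-like cells all 8 CD8 T cell genes were higher, by 0.564 (camera adjusted p = 3.1e-06, and adjusted p = 0.0801 with an estimated correlation). The 3 that passed when adjusted over the list alone were the coreceptor chains Cd8a (0.547, SE 0.195) and Cd8b1 (0.458, SE 0.134) and the cytotoxic granule gene Nkg7 (0.681, SE 0.229). Of these cells, clusters 6 and 8 held 23.5% ± 7.27 and 25.8% ± 11.8 with GW3965 and 36.8% ± 12.7 and 19.5% ± 3.41 with 27HC, and of these 6 libraries cluster 8 exceeded cluster 6 only in GW3965 replicate 3. Here 50 of 130 list tests passed with the preset correlation, and 0 with an estimated correlation or with fry.

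**Figure D3:**
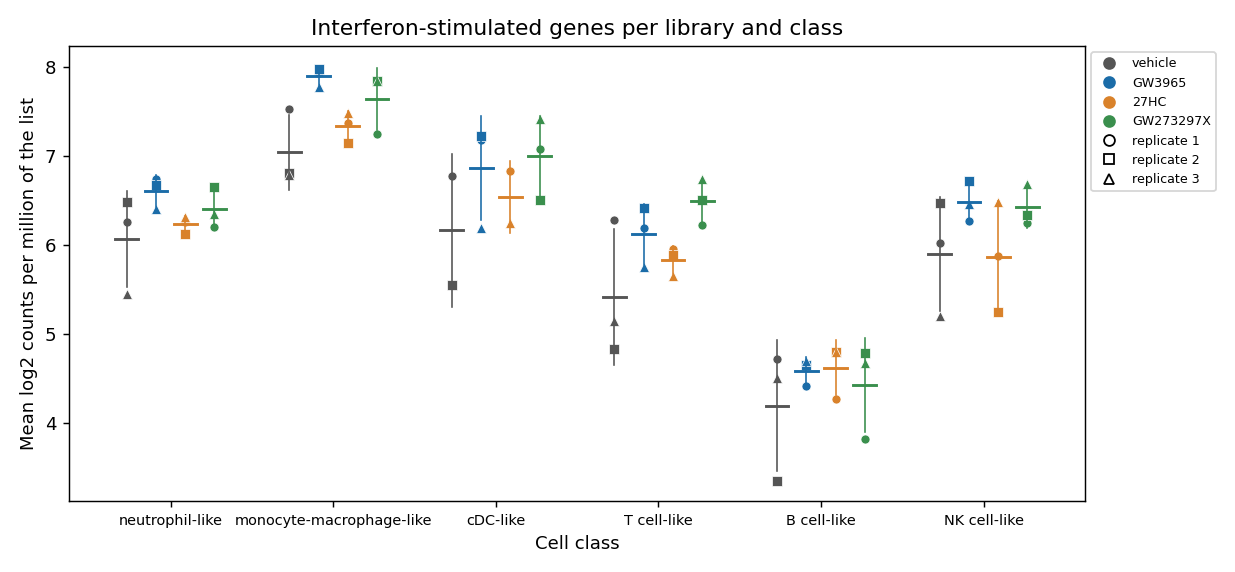
Mean level (log2 CPM) of the interferon-stimulated genes in each library, by cell class. Points are libraries, horizontal lines group means and vertical lines SDs (n = 3, or 2 for cDC-like cells of the vehicle and 27HC groups); in monocyte-macrophage-like cells the GW3965 libraries averaged 7.90, the 27HC libraries 7.34 and the vehicle libraries 7.04.

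A test across all 4 groups asks which genes differ at all between treatments. It called 1 of 61479 gene and class pairs, Krt83 in NK cell-like cells, with 2175 pairs at an unadjusted p under 0.05 by edgeR and 31 calls by DESeq2. Those 31 were all in other classes: DESeq2 called 0 genes in NK cell-like cells, so the call of Krt83 was lost there. Krt83 averaged 8.8, 25.9, 18.1 and 23.9 CPM with vehicle, GW3965, 27HC and GW273297X.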

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

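Among the cells left out of every comparison, cluster 27 drew attention because 1 treated library held more of it than any vehicle library. Its leading genes included Ms4a4c, Ifi206, Serpina3g and Ifi44, and its markers were those of B cells. It made up 2.43% of the cells of 27HC replicate 2 (122 of 5027 cells; 95% exact binomial interval 2.02 to 2.89), against 1.25% in vehicle replicate 3, the highest of the vehicle libraries (55 of 4390; 0.945 to 1.63). The difference between these libraries was not tested further.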

How the results depend on the processing

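The limits include 3 libraries per group that differed widely in their mix of cells, and few cells in some classes (14 to 56 per library for cDC-like cells). The shares kept their outcome, 0 changed classes, under every alternative run for them (8 classes at a Leiden resolution of 0.5 and 11 with no filter, without DESeq2), and so did the 0 calls of neutrophil- and monocyte-macrophage-like cells apart from those given here; the cause was not tested for any of the changes that follow, beyond the fewer libraries of some fits. Under settings other than a left-out library, 160 values of counts and lists stayed, 23 moved and 5 reversed, and of single genes 467 stayed, 10 reversed, 13 became stronger and 3 weaker. Of those 13, DESeq2 called Phlda1, Selenom and Cd40lg for GW3965, Folr2 for 27HC, Zmynd15, Ttc28, Nampt and Vmp1 for GW273297X, and Capg, Cd4 and Dqx1 for GW3965 vs 27HC. The fit without the 4 thymocyte-rich libraries keeps 1 library of GW3965, whose spread is taken from the other groups. In cDC-like cells it also keeps only 1 library of vehicle and 1 of 27HC. Planned results for alveolar macrophage-like cells have no value, and ILC2-like cells formed no class of their own at a Leiden resolution of 0.5.

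Without the thymocyte-rich libraries, neutrophil-like cells had 1 call for GW3965 vs vehicle and 1 for GW3965 vs 27HC. DESeq2 called 1 gene in monocyte-macrophage-like cells for 27HC and 2 for GW273297X. In cDC-, T, B and NK cell-like cells together, the 1 call of GW3965 vs vehicle became 8 with DESeq2, 228 with no filter on low counts, 2 with the replicate block, 0 with the 2 groups only, 30 without the thymocyte-rich libraries and 3 with the thymocyte share as covariate. The 0 of 27HC became 137 with no filter and 16 without the thymocyte-rich libraries. The 2 of GW273297X became 36 with DESeq2, 465 with no filter, 6 with the block, 8 with the 2 groups only and 69 without the thymocyte-rich libraries. The 0 of GW3965 vs 27HC became 3, 64 and 9 with DESeq2, no filter and without the thymocyte-rich libraries, and the 1 of the test across all groups became 31, 623 and 58 in the same order.

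The LXR list turned to -0.0146 with doublets kept and -0.0779 without the thymocyte-rich libraries for GW3965, to 0.0377 without those libraries and 0.0535 with their share as covariate for GW273297X, and to -0.181 without those libraries for GW3965 vs 27HC. With doublets kept, Abcg1 turned to -0.0059 and Mylip to -0.119 for GW3965, and Nr1h3 to 0.0563 and Scd2 to -0.0474 for GW273297X. Without the thymocyte-rich libraries, Apoe turned to 0.167 for 27HC, Abca1 to 0.242, Mylip to 0.0375, Nr1h3 to 0.338 and Apoe to 0.00729 for GW273297X, and Srebf1 to -0.317 for GW3965 vs 27HC.

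With each library left out in turn, calls in cDC-, T, B and NK cell-like cells together ranged from 0 to 6 for GW3965 (highest without vehicle replicate 1), 0 to 4 for 27HC (vehicle replicate 1), 0 to 17 for GW273297X (vehicle replicate 2) and 0 to 1 for GW3965 vs 27HC (GW3965 replicate 1), and from 0 to 9 across all groups (vehicle replicate 1). The LXR list ranged from -0.0176 to 0.0641 for GW3965, -0.25 to 0.0178 for 27HC, -0.113 to 0.0454 for GW273297X and -0.0881 to 0.237 for GW3965 vs 27HC. For GW3965, Abca1 ranged from 0.447 to 1.21, Abcg1 from -0.000954 to 0.384, Srebf1 from -0.396 to 0.192, Mylip from -0.104 to 0.138, Nr1h3 from -0.968 to 0.0434, Apoe from -0.0304 to 0.38, Scd1 from -1.77 to 0.0553 and Scd2 from -0.0176 to 0.757. For 27HC, Abca1 ranged from -1.47 to -0.373, Abcg1 from -0.466 to -0.0491, Srebf1 from -0.415 to -0.151, Nr1h3 from -1.11 to -0.436, Mylip from -0.456 to 0.0541, Apoe from -0.411 to 0.109, Lpcat3 from -0.0287 to 0.116, Scd1 from -1.35 to 0.494 and Scd2 from 0.321 to 1.09. For GW273297X, Abca1 ranged from -0.534 to 0.247, Abcg1 from 0.0939 to 0.447, Srebf1 from -0.0902 to 0.184, Mylip from -0.201 to 0.0454, Nr1h3 from -0.529 to 0.341, Apoe from -0.53 to 0.0167 and Scd2 from -0.33 to 0.629. For GW3965 vs 27HC, Abcg1 ranged from 0.264 to 0.621, Apoe from 0.0835 to 0.518, Scd1 from -0.79 to -0.149, Scd2 from -0.627 to -0.0313, Srebf1 from -0.156 to 0.449, Mylip from -0.0303 to 0.491 and Nr1h3 from -0.118 to 0.84.

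Libraries that share a replicate number were not closer to each other. Of 24 pairs of class and comparison, 1 had every correlation of its numbers over 0.1, correlations ran from -0.578 to 0.557, and in 37 of 139 comparisons of a library within a class it lay closest to its own number. The block kept Krt83 and Osgin1, called Zmynd15 in cDC-like cells for GW273297X (-2.45, edgeR adjusted p = 0.000871) and moved list calls from 52, 41, 75 and 50 of 130 to 55, 42, 74 and 52. With the block and an estimated correlation, 1 list passed where 0 did without the block, the SREBP2 list in NK cell-like cells for GW3965 (camera adjusted p = 0.0311 with an estimated correlation).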

Other observations

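Further lists were higher in monocyte-macrophage-like cells with GW273297X under the preset correlation alone. All 18 genes of aged or tumor-associated neutrophils were higher, by a median log2 fold change of 0.496 (camera adjusted p = 4.61e-07, and adjusted p = 0.141 with an estimated correlation). The plan was to read this list in neutrophil-like cells, so its value here is not assigned to monocytes or macrophages. Alternative activation and immunosuppression genes were higher by 0.45 (16 of 19 genes; camera adjusted p = 1.34e-06, and adjusted p = 0.141 with an estimated correlation), or by 0.677 without vehicle replicate 1. MHC class II genes, which present antigen to CD4 T cells, were higher by 0.462 (14 of 15 genes; camera adjusted p = 5.17e-06, and adjusted p = 0.232 with an estimated correlation), or by 0.162 without vehicle replicate 1 and 0.752 without vehicle replicate 3.

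Neutrophil-like cells held more T cell activation RNA with GW3965 (median 0.958, 17 of 19 genes; camera adjusted p = 1.18e-08, and adjusted p = 0.265 with an estimated correlation). Lists of T cell states were planned for T cell-like cells, so this RNA is not assigned to neutrophils. Immediate-early genes were lower in monocyte-macrophage-like cells with 27HC, by -0.368 (17 of 19 genes; camera adjusted p = 0.00225, and adjusted p = 0.577 with an estimated correlation). That call was lost without vehicle replicate 1 (-0.165), and the median was -0.622 without vehicle replicate 2. Gamma-delta and IL-17 T cell genes were higher in those cells with GW3965 than with 27HC, by 0.552 (6 of 7 genes; camera adjusted p = 0.00469, and adjusted p = 0.249 with an estimated correlation). That value was 0.334 without GW3965 replicate 1 and 0.337 without GW3965 replicate 3, and the call was lost without 27HC replicate 3 (0.495, camera adjusted p = 0.085). This list too was planned for T cell-like cells, so its value is not assigned to monocytes or macrophages. Erythrocyte RNA in B cell-like cells was lower with 27HC by -7.89 (all 5 genes; camera adjusted p = 0.00133, and adjusted p = 0.662 with an estimated correlation), and stood at 0.433 without vehicle replicate 3. RNA that marks epithelium had fewer than 5 tested genes in every class and was not tested. In neutrophil-like cells 4 called lists had a test whose sign differed from their median or mean. For GW3965 these were the SREBP2 list (median 0.00973, mean -0.0404, test upward; adjusted p = 0.601 with an estimated correlation) and the cell cycle list (-0.161, -0.186, upward; adjusted p = 0.621 with an estimated correlation). For GW273297X they were the CD8 T cell list (0.159, -0.0754, upward; adjusted p = 0.331 with an estimated correlation) and the B cell RNA list (-0.0817, -0.00697, upward; adjusted p = 0.554 with an estimated correlation).

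The tests that follow were chosen after the results they weigh had been seen, apart from the test for a clone of immature T cells.

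Clusters with thymocyte genes made up 68.6%, 63.0%, 34.1% and 19.7% of 4 libraries from 3 groups. A treatment effect is argued against by the 68.6% of vehicle replicate 2, beside 1.30% and 0.592% in the other vehicle libraries. A single clone sharing 1 recombined beta chain gene would have given more than 50% of the T cell receptor beta UMIs to 1 variable gene. The most used gene, Trbv2, took at most 27% (27HC replicate 3, interval 23.5 to 30.8), which argues against such a clone as the whole cause. It also misses the bound of under 25% written beforehand for no clone. In T cell-like cells Trbv2 took up to 24.1% (GW273297X replicate 3). In these libraries 21 to 24 variable genes were seen, although 3' libraries read little of this segment. A clone that arose before this recombination would not share 1 variable gene, so the test cannot exclude it. Thymus taken along with the lung would bring all stages of T cell development, and 6 or 7 of 7 T-lineage clusters held at least 1% of these cells in every such library, a value that cannot tell thymus from an expanded immature T lineage. No library label names the thymus or a leukaemia, so the source stays open.

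Interferon-stimulated genes in monocyte-macrophage-like cells were higher in all 3 treated groups than in the shared vehicle libraries. A single vehicle library could have set this. Leaving out vehicle replicates 1, 2 and 3 in turn left 141%, 91.5% and 78.9% of the difference for GW3965. For GW273297X it left 170%, 99.4% and 82.8%, and both sets of values argue against a single library. For 27HC it left 230%, 54.6% and 45.6%. The 45.6% goes with a single library, but the 54.6% and 230% show that the 27HC difference moved with each vehicle library. The share of thymocyte-gene cells as a covariate left 102%, 105% and 94.6% for GW3965, 27HC and GW273297X, which argues against that share. Since the vehicle libraries are shared, the 3 differences are not 3 independent findings. A treatment effect of GW3965 and GW273297X remains possible, and the adjusted p with an estimated correlation (0.0821 and 0.183) leaves it unproven.

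B cell RNA in monocyte-macrophage-like cells was lower in all treated groups. Without vehicle replicate 3, in which 43.9% of the cells were B cell-like, 30%, 39.2% and 1.65% of the difference was left for GW3965, 27HC and GW273297X, so most of it rests on that library. RNA released by B cells of the same library would make the share of B cells and this RNA rise together over the 12 libraries, and they did so by Pearson (r = 0.738, permutation p = 0.0109, two-sided, 1 relation tested; r = 0.616 without vehicle replicate 3 and 27HC replicate 2) and not by Spearman (rho = 0.497, permutation p = 0.104), which leaves this source open.

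The 6 libraries of each comparison were also split into 3 and 3 in all 10 ways, too few to give a p below 0.1. Where the real count is 0, every split meets it by construction, so the 10 of 10 given for such counts carry no information. Splits with at least as many calls as the real one (0) numbered 10 of 10 in neutrophil-like cells for every comparison, with 0 the highest of the others, and 10 of 10 in monocyte-macrophage-like cells, where another split called up to 1, 267, 0 and 0 genes for GW3965, 27HC, GW273297X and GW3965 vs 27HC. In the other 4 classes the real calls were 1, 0, 2 and 0, met by 4, 10, 4 and 10 of 10 splits, with up to 95, 50, 6 and 0 calls in another. Shares had 10 of 10 in each, with up to 3, 0, 0 and 0 changed classes in another. The LXR list was met in size by 9, 3, 5 and 4 of 10 splits, with values up to 0.2848, 0.2276, 0.2198 and 0.2525. Across all groups, 24 of 40 splits called at least as many pairs as the real 1, and another called 2570. The splits with many calls point to a structure of the samples other than the treatments, and its source stays open. Libraries rich in thymocyte-gene cells lay together in the split with 267 and 50 calls for 27HC, but the other splits for 27HC with both such libraries together called 0, 13 and 5 genes over all classes, and 1 that parted them called 21. The split with 2570 had 3 of the 4 such libraries in 1 part, and another split across all groups that did so called 0.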
